A study of Homo sapiens with 36 samples.

How the data were processed

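Whole-transcriptome RNA signal was measured on Affymetrix arrays in MEC-1, an established human B-cell line derived from chronic lymphocytic leukaemia. Per the labels, cells took up LNA gapmers, which are short antisense oligonucleotides that direct RNase H to a target RNA, without a transfection reagent (gymnosis), at 1 µM of each gapmer for 4 days. Each of 3 long non-coding RNAs had its own experiment: CYTOR (also called LINC00152), LINC00158 and RP11-161H23.5. Each experiment had 4 groups of 3 arrays, namely a scrambled gapmer, gapmer 1, gapmer 2 and both gapmers together (gapmer 1+2). That made 36 arrays in 12 groups. As the labels give the dose per gapmer, the total amount of oligonucleotide may be higher with gapmer 1+2 than in the other groups. The labels call the arrays of a group replicates without saying whether they came from separate cultures. Every p-value below therefore measures the spread between these arrays only.

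The deposited values are log2 signals for 135750 array units, made with RMA in Affymetrix Expression Console per the submitters' processing notes. The versions of both, the genome build and whether all arrays were summarised together are not given in the sources used here. The log2 scale was read from the values, which ran from 1.96 to a ceiling of 19.93. Between 162 and 252 units per array sat at the ceiling, 125 of them on every array, so the change of a unit at the ceiling in both groups is not measured, and that of a unit at it in 1 group is a lower bound of its size. An array gives no read depth, and its number of replicates limits the precision.

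Gene symbols came from the array's own unit table. A single symbol was given for 36176 units, several for 1119 and none for 98455. The single symbols covered 33616 different genes, and none was changed through the gene table. Units with several symbols or none were tested but not named, and of units with the same symbol the brightest was named. No coordinates are given, since the build of the array table is not named. A RefSeq gene table (assembly GRCh38.p14) was used only for gene classes and to find genes within 500 kb of a target.

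Within each experiment, units with a mean at or above the median of all units were kept, and the targets were always kept. A model with 4 group means was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. It had 8 residual degrees of freedom and between 3.11 and 3.44 prior degrees of freedom. A unit was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The contrasts were each treatment against scrambled, gapmer 1 against gapmer 2, and gapmer 1+2 against the mean of the single gapmers. Single values of the targets were also compared by an exact two-sided permutation test, which cannot go below p = 0.1 with 3 arrays against 3. The 3 scrambled groups were compared with each other in a fit of the 9 scrambled arrays. Overlaps of calls were set beside the number for independent lists and beside 20 simulations without any treatment change, which keep the shared scrambled arrays.

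A total of 28 gene lists was fixed in advance: interferon response, nucleic acid sensing, NF-kB targets, B-cell receptor signalling, B-cell identity, plasma cell differentiation, B-cell activation and early response, MHC class I, MHC class II, mitosis, DNA replication, replication-dependent histones, p53 targets, BCL2 family and caspases, MYC targets and ribosome biogenesis, cytosolic ribosomal proteins, integrated stress response, unfolded protein response, heat shock and proteasome, oxidative stress response, cholesterol biosynthesis, glycolysis and hypoxia, oxidative phosphorylation, lysosome and autophagy, and markers of T and NK cells, myeloid cells, erythroid cells and platelets, and stromal and epithelial cells. The lists were tested with camera (preset inter-gene correlation 0.01) over 9 treatment contrasts, which gave 252 tests adjusted together. The same tests were run with fry and with camera at an estimated correlation. List members were also adjusted over the list alone.

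The samples, groups, comparisons, lists, filter and named-gene rule, and the first group of alternatives given below, were chosen before the data were examined. The rule for naming genes took the target; the 10 highest and 10 lowest mean changes among named units called the same way in all 3 treatments; for each treatment the 3 highest and 3 lowest called units whose treated arrays all lay on one side of the scrambled arrays; up to 4 called members per list, or the 2 with the largest change where none was called; neighbours of the target; and the 10 highest and 10 lowest units shared between experiments. Exceptions are named as such.

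Those alternatives were no filter, a filter at the 75th percentile, quantile normalization of the 12 arrays on top of the deposited values, eBayes with trend and robust, all 36 arrays in one fit, only the groups in the contrast, the replicate number as a block, each array left out in turn, the mean of all units of a gene, and an estimated correlation. Chosen after seeing the data were scrambled arrays of the other experiments as controls, gene lists matched on level (10000 random lists each), and fits without 1 array that stood apart. Comparisons with scrambled arrays of other experiments came from a joint fit of all 36 arrays, unlike the main fits of 12. Identical values between arrays were also counted after seeing the data, over 7583 units with a mean of at least 8 that never reached the ceiling.

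The fit was tested on simulated data with 100 changed units per step. For gapmer 1 against scrambled, a change of 2 on the log2 scale was recovered for 69% of units in the CYTOR experiment (67888 units), 68% in the LINC00158 experiment (67877 units) and 66% in the RP11-161H23.5 experiment (67896 units). A change of 1 was recovered for 14%, 7% and 8%. False calls numbered 3, 2 and 2. The adjustment of p is stricter where few units change, and far more units were called in the real data. These shares therefore do not give the recovery in the real comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The array holds no unit named for RP11-161H23.5, so no value is given for that target.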

Results

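RNA signal was measured in MEC-1 cells after gapmers against each of 3 long non-coding RNAs, with 36 arrays in 12 groups of 3. Median log2 signal was lower in the CYTOR treatments, at 3.84 ± 0.03, 3.89 ± 0.02 and 3.87 ± 0.02 (SD, n = 3) with gapmer 1, gapmer 2 and gapmer 1+2, against 4.06 ± 0.03 with scrambled gapmer. In the other 2 experiments it lay between 3.95 and 4.02 with the treatments, against 4.02 and 4.03 with scrambled gapmer. There the bright units differed instead. Bright units in this comparison were the 1927 with a mean of at least 12 that never reached the ceiling. Their median per array, averaged over 3 arrays, was taken for each group. In the LINC00158 experiment it was 14.63 ± 0.07 (SD, n = 3) with scrambled gapmer and 13.86 ± 0.49, 13.81 ± 0.11 and 13.97 ± 0.23 with gapmer 1, gapmer 2 and gapmer 1+2. In the RP11-161H23.5 experiment it was 14.20 ± 0.12 with scrambled gapmer and 13.89 ± 0.16, 13.88 ± 0.03 and 13.69 ± 0.17 with the treatments. In the CYTOR experiment it was 14.43 ± 0.25, against 14.59 ± 0.15, 14.45 ± 0.19 and 14.59 ± 0.06. Arrays of a group differed from each other by a mean absolute log2 difference of 0.32 to 0.54.

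The arrays fell into 4 sets of 9 by the values they shared exactly. The 9 scrambled arrays of all 3 experiments made 1 set, and the 9 treated arrays of each experiment made the other 3. At least 2.39% of 7583 bright units held the same value, to the 2 deposited decimals, on any 2 arrays of a set, and at most 0.870% on 2 arrays of different sets. Closeness in signal did not give this order. Scrambled groups of different experiments lay 0.48 to 0.71 apart (mean absolute log2 difference) with 3.84% to 4.64% identical values, whereas scrambled and treated groups lay 0.54 to 1.17 apart with 0.305% to 0.595%. Each set held scrambled arrays only or treated arrays of 1 experiment only, so no treated-against-scrambled value could be computed within a set. For every such comparison the set and the treatment cannot be told apart, and "higher" and "lower" below describe the arrays. Comparisons between the treatments of an experiment, and between scrambled groups, lie within a set.

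**Figure D1:**
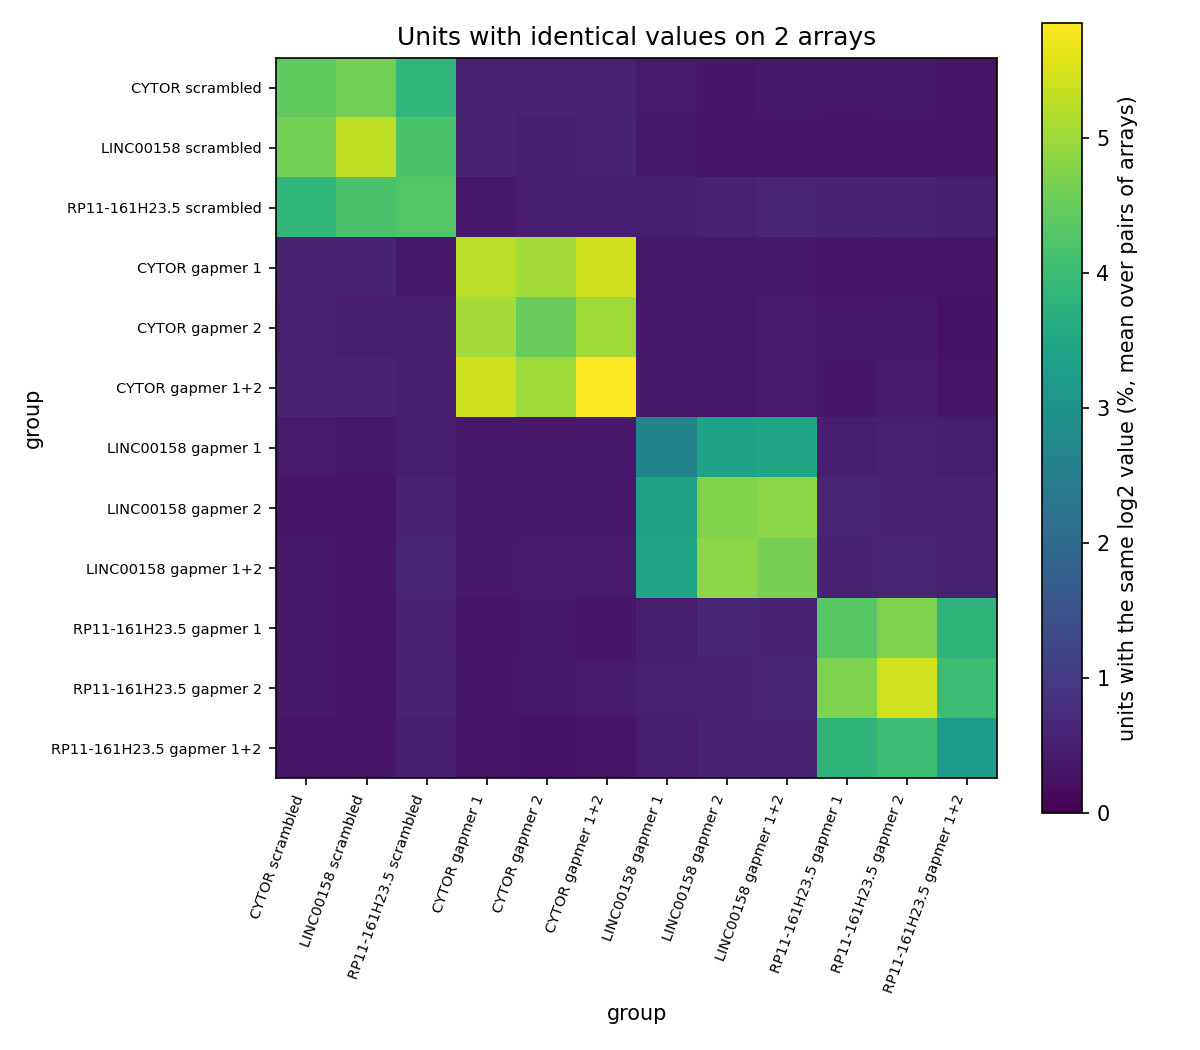
Each cell gives the mean percentage of bright units with identical log2 values on 2 arrays, for each pair of the 12 groups (both axes). Scrambled groups shared 3.84% to 4.64% with each other and 0.305% to 0.595% with treated groups.

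The CYTOR experiment asked what changes when CYTOR, a long non-coding RNA, is silenced. The unit named for the target was higher, not lower, in the arrays labelled with CYTOR gapmers. It read 5.34 ± 0.14 (SD, n = 3) with scrambled gapmer, 6.93 ± 0.47 with gapmer 1, 6.56 ± 0.25 with gapmer 2 and 6.27 ± 0.21 with gapmer 1+2. The changes were 1.59, 1.21 and 0.92 (SE 0.24; adjusted p = 0.00385, 0.0104 and 0.0360), with all 9 treated arrays above the 3 scrambled arrays (exact permutation p = 0.1 each, the smallest possible). The call for gapmer 1+2 was lost with the replicate number as a block (adjusted p = 0.0599) and when any 1 of its 6 arrays was left out (adjusted p from 0.0539 to 0.113). Against the scrambled arrays of the LINC00158 experiment, a comparison chosen after seeing the data, the changes were 0.72, 0.35 and 0.057, none of them called. Against those of the RP11-161H23.5 experiment they were 2.11, 1.74 and 1.45, all called (adjusted p = 6.5e-06, 8.01e-05 and 0.000525). Both comparisons came from a joint limma fit of all 36 arrays. In that fit the adjusted p against the scrambled arrays of its own experiment was 0.000373, 0.00402 and 0.0289. The unit's scrambled level of 5.34 lay between 6.21 in the LINC00158 and 4.82 in the RP11-161H23.5 experiment. MIR4435-2HG, a gene with near-identical sequence, was lower (-0.73, -0.83 and -0.79, SE 0.18; adjusted p = 0.0276, 0.0157 and 0.0244).

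Other genes moved further in the same arrays. OR10Q1, an olfactory receptor gene, rose from 3.53 ± 0.10 to 6.80, 6.87 and 6.95 (changes 3.27, 3.34 and 3.43, SE 0.18). RPPH1, the RNA component of RNase P, rose by 3.40, 3.00 and 3.43 (SE 0.58) from a variable scrambled level of 8.41 ± 1.56. CDK2, a kinase of the G1/S transition and S phase, rose by 1.93, 1.29 and 1.19 (SE 0.32). Other units with the highest mean changes in all 3 treatments were MIR548AE2 (mean 3.12), FBXO43 (2.17), CLN6 (1.89), TBC1D2B (1.82), BCL2L12 (1.53), EFL1 (1.48) and KLHL25 (1.48). ISL1, a homeobox transcription factor, was lower (-2.14, -2.68 and -2.22, SE 0.23). The lowest mean changes were otherwise in small RNA genes and pseudogenes, among them MIR548AC (-2.49), MIR548AA2 (-2.44), H3P38 (-2.33), MIR4740 (-2.32, and -1.26 without scrambled replicate 1), SNORD82 (-2.31) and RPL36AP21 (-2.21). By class, 80 of 741 microRNA units (10.8%) were lower in all 3 treatments, against 418 of 13394 protein-coding units (3.12%). The share was 6.43% of lncRNA units, 6.14% of pseudogene units and 6.22% of units without a single gene name. Of all 67888 units, 3870 were lower. Dim units fell most, with a median change of -0.26 in the bins of mean signal from 4 and from 6, and 0.0017 in the bin from 12. Class was not separated from signal level, and no test between classes was run. None of 6 measured genes within the neighbour window of CYTOR was called by limma (lowest adjusted p = 0.193).

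The DNA replication list was called higher in all 3 CYTOR treatments by camera at its preset correlation. This call, and those of the histone, ribosomal protein and MYC target lists, did not hold with an estimated correlation (adjusted p = 0.777 for each). Relative to the median of all named genes, the median of the 29 measured members was 0.46, 0.38 and 0.45 higher (camera adjusted p = 0.000406, 0.00198 and 0.000674). Members called higher and lower were 4 and 0, 2 and 1, and 1 and 0, with the same counts adjusted over the list alone. MCM10, a replication initiation factor, rose by 1.01, 0.85 and 1.00 (SE 0.20), and MCM7, a subunit of the replicative helicase, rose by 0.97 with gapmer 1. Replication-dependent histones had medians 0.78, 0.64 and 0.90 above other genes (18 members; adjusted p = 0.000401, 0.000824 and 2.39e-06, and 0.777 with an estimated correlation), though after quantile normalization the call for gapmer 2 was lost (adjusted p = 0.0545). H2AC8 rose by 1.70 ± 0.46 (SE) with gapmer 1, with a mean over the treatments of 1.37 that was 0.80 without scrambled replicate 1. With gapmer 2 the single called member, H3C8, fell by 1.20 ± 0.32. With gapmer 1+2, 2 histone genes were called, H4C2 (1.10) and H2BC7 (1.03), and 7 adjusted over the list alone. Cytosolic ribosomal proteins were 0.37, 0.46 and 0.45 above other genes (21 members; adjusted p = 0.00257, 0.000119 and 0.000674, and 0.777 with an estimated correlation), all 3 calls being lost after quantile normalization (0.527, 0.148 and 0.334). Their medians lay inside the central 95% of random lists matched on level (percentiles 52.8, 92.1 and 91.9). Members called higher and lower were 2 and 0, 2 and 0, and 2 and 1 (5 and 1, 6 and 1, and 4 and 1 adjusted over the list alone). RPL18 rose by 1.20, 1.03 and 1.06 (SE 0.21), while RPL5 fell by 1.46 ± 0.37 (SE) with gapmer 1+2. The list of MYC targets and ribosome biogenesis was called higher with gapmer 1 (median 0.55; adjusted p = 0.000674, and 0.777 with an estimated correlation; 3 of 18 members called, 3 adjusted over the list alone) and with gapmer 1+2 (0.44; adjusted p = 0.0269, lost after quantile normalization at 0.134 and with an estimated correlation at 0.777). FBL, a nucleolar RNA methyltransferase, rose by 0.75, 0.81 and 0.63 (SE 0.14), and MYC itself rose by 1.22 with gapmer 1.

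The interferon response list was called lower with gapmer 2 and gapmer 1+2 at the preset correlation, but not with an estimated correlation (adjusted p = 0.777 for both). With gapmer 2, 10 of 28 members were lower and 0 higher (11 lower adjusted over the list alone; camera adjusted p = 0.00675), and with gapmer 1+2, 7 of 28 (8 adjusted over the list alone; adjusted p = 0.0134). SAMD9L, an interferon-induced restriction factor, was lower (-1.26, -1.73 and -1.82, SE 0.32), and IFIT1, which binds viral RNA, was lower (-1.18 and -1.21, SE 0.22) with gapmer 2 and gapmer 1+2. With gapmer 1 the list was not called (adjusted p = 0.958), with 3 members lower, SAMD9L, RSAD2 (-0.96, SE 0.19) and OASL (-0.75, SE 0.16), and 1 higher, ISG15, which rose by 1.09 ± 0.28 (SE). The difference between the gapmers was not called for any single unit.

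Several lists were called higher with CYTOR gapmer 1. For each of them the adjusted p was 0.777 with an estimated correlation. For the integrated stress response the median was 0.57 above other genes (adjusted p = 0.000114; 4 of 26 members higher and 1 lower, the same adjusted over the list alone). SLC7A5, an amino acid transporter, rose by 1.18 ± 0.23 (SE) and DDIT4, an mTORC1 inhibitor, by 1.26 ± 0.34. The lysosome and autophagy list was 0.51 higher (adjusted p = 0.00539; 2 of 19, 2 adjusted over the list alone), with CTSA, a lysosomal carboxypeptidase, up by 1.46. The B-cell receptor signalling list (0.35; 0.00599; 1 of 19 called), the activation list (0.30; 0.0269; 1 of 20) and the glycolysis and hypoxia list (0.31; 0.0107; 2 of 24) were called too. Calls lost after quantile normalization were plasma cell differentiation (0.48; 0.00826, then 0.0658), B-cell identity (0.38; 0.0143, then 0.0706), MHC class II (0.48; 0.0269, then 0.290), oxidative phosphorylation (0.40; 0.0108, then 0.268), unfolded protein response (0.33; 0.0162, then 0.367) and mitosis (0.16; 0.0310, then 0.171). The plasma cell genes JCHAIN and MZB1 rose by 1.34 and 0.94. In the other treatments, where that list was not called, members moved both ways: MZB1 rose by 1.06 with gapmer 1+2, PRDM1 was lower with gapmer 2 and gapmer 1+2 (-1.46 and -1.43, SE 0.32), and CD38 fell by 1.15 with gapmer 1+2. Beside random lists matched on level, the 6 calls lost after quantile normalization lay inside the central 95%, as did B-cell receptor signalling (percentile 88.5) and glycolysis and hypoxia (93.8). With gapmer 1+2, the unfolded protein response (adjusted p = 0.00539, then 0.169) and mitosis lists (0.0269, then 0.136) were called and lost in the same way (percentiles 91.0 and 85.4; adjusted p = 0.777 with an estimated correlation), and KIF23, a kinesin of cytokinesis, rose by 1.23, 1.30 and 1.06 (SE 0.22) over the treatments.

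In total, limma called 8909 units with CYTOR gapmer 1 (1202 higher, 7707 lower), 9657 with gapmer 2 (1246 higher, 8411 lower) and 7104 with gapmer 1+2 (1044 higher, 6060 lower). At least a 2-fold change was shown by 5209, 5733 and 4155 of them. The excess of lower units went with a shift of the median unit by -0.23, -0.26 and -0.20, and after quantile normalization the split was 2033 to 2049, 2303 to 2318 and 1468 to 1441. No unit called both before and after quantile normalization changed direction. Many calls were lost, however. Kept were 2025, 2306 and 1423 of the lower calls and 1092, 1192 and 945 of the higher calls. MNDA, from the list of myeloid markers, was lower (-1.47, -1.88 and -1.68, SE 0.29). With any 1 array left out, and so fewer arrays, the counts were smaller: at the lowest 4334 without gapmer 1 replicate 2, 6019 without gapmer 2 replicate 1 and 3027 without gapmer 1+2 replicate 1, and at the highest 7117, 7902 and 5070. They were 4729, 2484 and 3665 with only the groups of the contrast in the fit, 4554, 5288 and 3340 with a filter at the 75th percentile, and 17780, 16439 and 16618 against the RP11-161H23.5 scrambled arrays (5662, 4606 and 5757 higher). Against the LINC00158 scrambled arrays gapmer 2 and gapmer 1+2 gave 14965 and 10905. Counts against other scrambled arrays came from a joint fit of all 36 arrays. In that fit the CYTOR scrambled arrays themselves gave 11645, 12439 and 9797. These comparisons are between arrays of different sets.

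**Figure D2:**
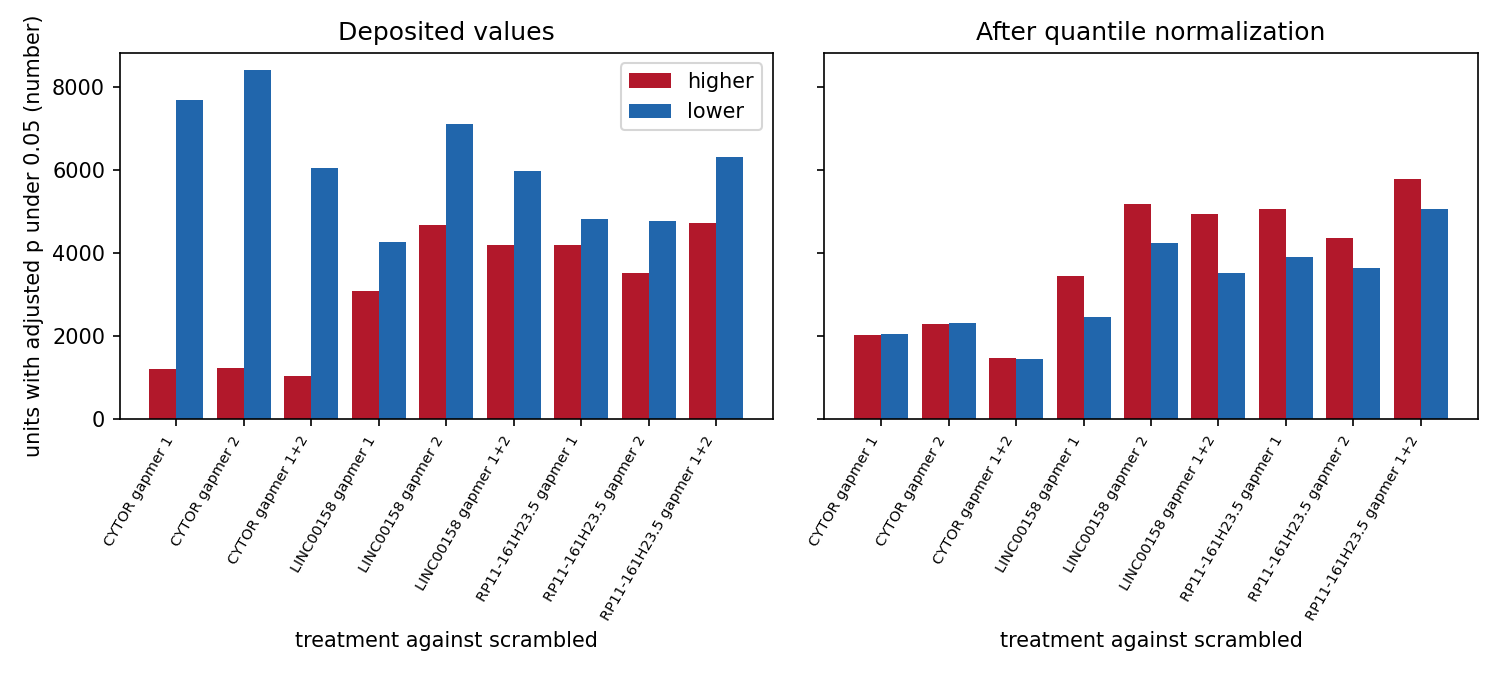
Bars give the number of units called higher or lower at adjusted p under 0.05 for each treatment against scrambled, from the deposited values and after quantile normalization. The CYTOR calls, 7707 lower with gapmer 1, became nearly even after quantile normalization (2033 higher, 2049 lower).

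The LINC00158 experiment asked the same of LINC00158, and here the unit of the target was lower. It read 7.94 ± 0.75 (SD, n = 3) with scrambled gapmer and 5.57 ± 0.31, 6.01 ± 0.41 and 5.32 ± 0.52 with gapmer 1, gapmer 2 and gapmer 1+2. The changes were called in each treatment (-2.36, -1.92 and -2.62, SE 0.39; adjusted p = 0.00710, 0.0107 and 0.00385), with exact permutation p = 0.1 each, the smallest possible. The unit was also lower in the RP11-161H23.5 experiment (-1.15, -1.34 and -1.44, SE 0.29; adjusted p = 0.0252, 0.0140 and 0.00794). There it read 5.65, 5.46 and 5.36 with the treatments, close to its levels with its own gapmers. In the CYTOR experiment the unit's changes were 0.13, -1.04 and -1.21 (SE 0.37, adjusted p = 0.855, 0.0837 and 0.0605), none of them called. A fall particular to the LINC00158 gapmers was therefore not shown. With only the groups of the contrast in the fit, the call for LINC00158 gapmer 1 was lost (adjusted p = 0.0650). Against the CYTOR scrambled arrays, chosen after seeing the data, the changes were smaller (-1.52, -1.08 and -1.77; adjusted p = 0.00661, 0.0411 and 0.00159). Against the RP11-161H23.5 scrambled arrays they were -1.23, -0.79 and -1.49, and the call for gapmer 2 was lost (adjusted p = 0.0300, 0.167 and 0.00993). Both comparisons came from a joint limma fit of all 36 arrays. In that fit the adjusted p against the scrambled arrays of its own experiment was 7.6e-05, 0.000476 and 1.67e-05. Of 10 measured genes near LINC00158, JAM2, a junctional adhesion protein, was lower (-0.91, -0.93 and -1.14; adjusted p = 0.0402, 0.0286 and 0.0148), and ATP5PF, a subunit of ATP synthase, was lower (-1.04, -1.24 and -1.03; adjusted p = 0.0487, 0.0209 and 0.0430), both in the fit without a filter. After quantile normalization ATP5PF was at -0.48 with gapmer 1 and -0.55 with gapmer 1+2.

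Both antigen presentation lists were called lower in all 3 LINC00158 treatments. The adjusted p was 0.777 with an estimated correlation in each case. For MHC class I, medians lay at -1.04, -1.52 and -1.21 relative to all named genes (camera adjusted p = 0.00297, 0.00114 and 0.00112), with 4, 8 and 10 of 13 members called lower and 0 higher (10, 11 and 10 adjusted over the list alone). HLA-B was lower (-2.33, -3.01 and -2.39, SE 0.68), and TAPBP, which loads peptides onto class I molecules, was lower (-1.75, -2.23 and -1.93, SE 0.45). For MHC class II, medians lay at -0.88, -1.16 and -1.11 (adjusted p = 0.000824, 0.000406 and 0.000674, and 0.777 with an estimated correlation), with 5, 11 and 9 of 13 members lower (12, 13 and 11 adjusted over the list alone). HLA-DRB5 was lower (-2.15, -2.70 and -2.36, SE 0.41), and CIITA, the class II transactivator, was lower (-1.65, -2.05 and -1.60, SE 0.45; after quantile normalization -1.16, -1.47 and -1.04).

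The interferon response and NF-kB lists were called lower too. With an estimated correlation, adjusted p = 0.786 for NF-kB targets with gapmer 1 and 0.777 for the others. Of 28 interferon response genes, 6, 11 and 7 were called lower (9, 14 and 12 adjusted over the list alone; camera adjusted p = 0.00782, 0.000674 and 0.00159), with gapmer 1 inside the central 95% of random lists matched on level (percentile 2.79). ISG15, a ubiquitin-like protein induced by interferon, was lower (-2.71, -2.99 and -2.79, SE 0.45), and MX1, an antiviral GTPase, was lower (-1.38, -2.05 and -1.73, SE 0.37; after quantile normalization -0.63, -1.22 and -1.06). Of 21 NF-kB targets, 3, 13 and 8 were lower (3, 16 and 14 adjusted over the list alone; adjusted p = 0.0335, 0.00142 and 0.00201), the call for gapmer 1 being lost after quantile normalization (0.0584). NFKB1, a subunit of the factor itself, was lower (-1.31, -1.84 and -1.90, SE 0.31).

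The lists of B-cell receptor signalling, B-cell identity and plasma cell differentiation were called in the same direction. Each had adjusted p = 0.777 with an estimated correlation. In B-cell receptor signalling, 3, 9 and 9 of 19 genes were lower (9, 14 and 12 adjusted over the list alone; camera adjusted p = 0.0108, 0.00245 and 0.00112). Beside random lists matched on level these 3 calls lay inside the central 95% (percentiles 5.50, 12.4 and 7.58). PIK3CD, the kinase subunit PI3K delta, was lower (-1.67, -2.03 and -1.94, SE 0.39), and CD79A, a chain of the receptor, was lower with gapmer 2 and gapmer 1+2 (-1.89 and -1.75, then -1.09 and -1.06 after quantile normalization). In the B-cell identity list, 1, 10 and 6 of 19 were lower (7, 16 and 10 adjusted over the list alone; adjusted p = 0.0269, 0.00336 and 0.00536, and 0.777 with an estimated correlation), and CD37, a tetraspanin, was lower (-1.99, -2.29 and -1.88, SE 0.44; after quantile normalization -1.28, -1.47 and -1.22). In plasma cell differentiation, 3, 10 and 6 of 16 were lower (9, 13 and 13 adjusted over the list alone; adjusted p = 0.00536, 0.00112 and 0.000895, and 0.777 with an estimated correlation), with gapmer 1 inside the central 95% (percentile 5.49). PRDM1, which drives plasma cell differentiation, was lower (-1.65, -1.98 and -1.86, SE 0.30). After quantile normalization the gapmer 1 calls of these 3 lists were lost (0.0679, 0.0993 and 0.0658).

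The integrated stress response, unfolded protein response and, in some treatments, histone and other lists were called lower as well. With an estimated correlation, adjusted p = 0.779 for heat shock and proteasome with gapmer 2 and 0.777 for the others. Of 26 integrated stress response genes, 7, 13 and 8 were lower (11, 18 and 13 adjusted over the list alone; camera adjusted p = 0.00826, 0.000716 and 0.00370; gapmer 1 lost after quantile normalization at 0.0692). SLC3A2, an amino acid transporter chain, was lower (-1.75, -1.98 and -2.03, SE 0.37), and SHMT2, a mitochondrial enzyme of serine metabolism, was lower (-1.71, -1.91 and -1.89, SE 0.38). After quantile normalization these were -1.12, -1.23 and -1.38 for SLC3A2 and -0.96, -1.09 and -1.22 for SHMT2. The unfolded protein response was called in all 3 treatments (2, 6 and 7 of 23; adjusted p = 0.0108, 0.00333 and 0.00357, and 0.777 with an estimated correlation), all lost after quantile normalization (0.375, 0.139 and 0.0869). SEC61B, a subunit of the translocon, was lower (-2.20, -2.40 and -2.16, SE 0.43). Replication-dependent histones were called with gapmer 1 and gapmer 1+2 (adjusted p = 0.0190 and 0.0162; the former lost after quantile normalization at 0.0835), and the linker histone H1-4 was lower (-2.79, -3.36 and -3.75, SE 0.46). Calls lost after quantile normalization were those of oxidative phosphorylation with gapmer 1 and gapmer 2 (0.0192 and 0.00438, then 0.199 and 0.0584), mitosis with gapmer 2 and gapmer 1+2 (0.0107 and 0.0269, then 0.214 and 0.281), the BCL2 family with gapmer 2 (0.0269, then 0.0702), and heat shock and proteasome with gapmer 2 (0.0437, then 0.411). Inside the central 95% of random lists matched on level were these last 6 calls and all 3 of the unfolded protein response (percentiles 51.6, 21.9 and 25.6), and those of the integrated stress response with gapmer 1 and gapmer 1+2 (20.2 and 2.74).

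Among single genes, MIR4740 rose from 5.79 ± 0.44 to 11.79 ± 3.00, 13.90 ± 0.04 and 13.96 ± 0.65 (SE of each change 1.08), with gapmer 1 replicate 1 at 8.33 against 13.33 and 13.71 on the other 2 arrays, although its scrambled level differed between experiments, at 7.08 ± 1.85 in the CYTOR and 12.19 ± 0.48 in the RP11-161H23.5 experiment. MYEOV, a gene overexpressed in some myelomas, rose from 5.55 ± 0.20 to 9.49, 9.77 and 10.16 (SE of each change 0.30). SOX10, a neural crest transcription factor, rose by 3.08, 3.53 and 3.33 (SE 0.27). Others with high mean changes were RN7SL395P (3.44), MIR6870 (3.10), MIR6860 (2.94), RNU7-136P (2.90), EIF1AXP2 (2.62) and JAZF1 (2.61). PCBP1, an RNA-binding protein, was at 15.49 with scrambled gapmer and at 12.44, 12.22 and 12.23 with the treatments. Mean changes were also low for H1-4 (-3.30), HSPB1P1 (-2.99), MAP2K2 (-2.97), COX8A (-2.77) and the 7SK copies RN7SKP204 (-4.09), RN7SKP111 (-4.08), RN7SKP203 (-3.74) and RN7SKP36 (-2.88). The 7SK and 7SL copies are near-identical in sequence, so the copy behind a signal is uncertain. Protein-coding units were lower in all 3 treatments in 974 of 12957 cases and higher in 105, while microRNA units were higher in 50 of 784 and lower in 15. Of all 67877 units, 2040 were higher and 2783 lower. Class was not separated from signal level here, and no test between classes was run. The myeloid marker FCN1 was lower (-1.87, -1.72 and -1.98, SE 0.20).

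Counts of called units were 7351 with gapmer 1 (3085 higher, 4266 lower), 11792 with gapmer 2 (4680 higher, 7112 lower) and 10188 with gapmer 1+2 (4200 higher, 5988 lower), with 4849, 7880 and 6766 changed at least 2-fold. Units in the bins of mean signal from 8 to 14 had median changes of -0.59 to -0.80, and quantile normalization brought every bin to between -0.10 and 0.03 and the split to 3448 to 2453, 5188 to 4240 and 4953 to 3538. The gapmer 1 count depended on single arrays: it was 17407 without gapmer 1 replicate 1 and 2133 without gapmer 1 replicate 3, and 164 with only its own groups in the fit. A filter at the 75th percentile gave gapmer 1 a count of 4795, and all 36 arrays in one fit gave gapmer 1 and gapmer 1+2 counts of 13297 and 15923. In that joint fit gapmer 2 gave 17267. Against the RP11-161H23.5 scrambled arrays, chosen after seeing the data, the joint fit gave 7546, 7985 and 6908. Against the CYTOR scrambled arrays it gave 9597, 12446 and 11162. With any 1 array left out the gapmer 2 count was 4888 (without scrambled replicate 1) to 7329 and the gapmer 1+2 count 3202 (without gapmer 1+2 replicate 2) to 6390. These comparisons too are between arrays of different sets.

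**Figure D3:**
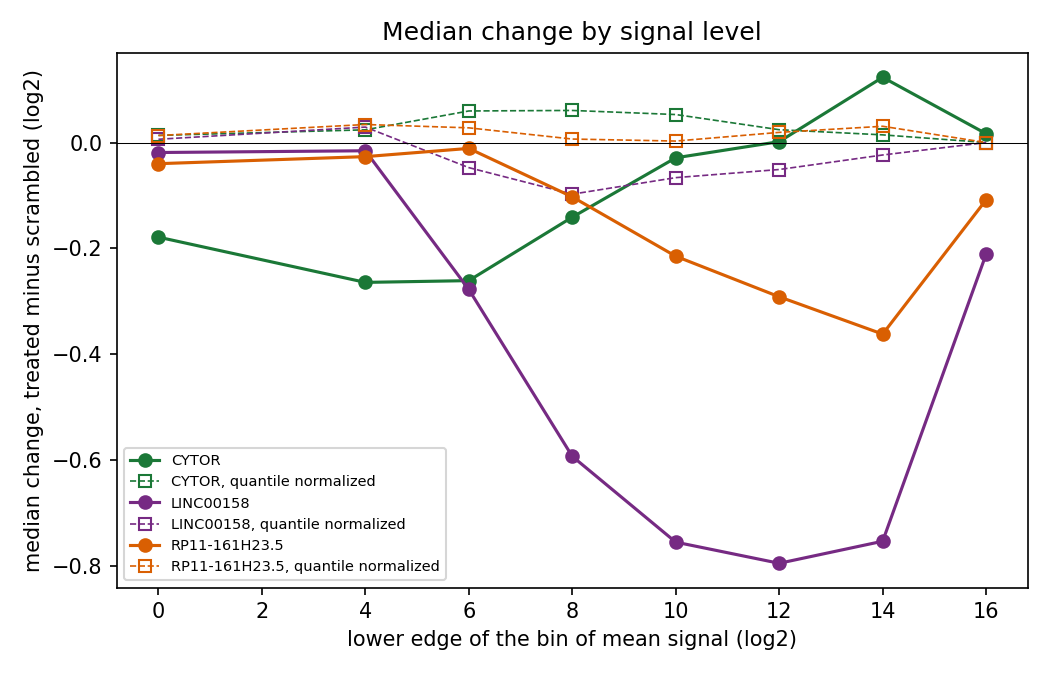
Lines give the median log2 change of treated against scrambled arrays by bin of mean signal (x axis, log2), for the 3 experiments as deposited and after quantile normalization. The LINC00158 experiment reached -0.80 in the bin from 12, and -0.05 there after quantile normalization.

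For RP11-161H23.5, the third long non-coding RNA, the target has no named unit, so its own level is not given. The DNA replication list was called higher and the MHC class I list lower in the arrays labelled with its gapmers, and the MHC class II list lower with gapmer 2 and gapmer 1+2. Each of these list calls had adjusted p = 0.777 with an estimated correlation, and those of MHC class I with gapmer 1 and of both MHC lists with gapmer 2 were lost after quantile normalization. MCM4, a helicase subunit, rose by 1.54, 1.42 and 1.65 (SE 0.24, n = 3) with gapmer 1, gapmer 2 and gapmer 1+2. HLA-DRB5, a class II chain, was lower (-1.48, -1.61 and -2.17, SE 0.23). MYEOV rose from 6.17 ± 0.40 to 10.06, 9.72 and 9.87 (SE of each change 0.27).

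The DNA replication and histone lists had adjusted p = 0.777 with an estimated correlation in each treatment. Among DNA replication genes, 1, 8 and 6 of 28 were called higher (1, 10 and 12 adjusted over the list alone), with medians 0.28, 0.54 and 0.68 above other genes (camera adjusted p = 0.0233, 8.01e-06 and 1.56e-05). CCNE2, a cyclin of S-phase entry, rose by 1.20 and 1.51 (SE 0.26) with gapmer 2 and gapmer 1+2, and CDC6, a licensing factor, rose by 1.20 and 1.07 (SE 0.30). Replication-dependent histones were called higher as a list (adjusted p = 0.0380, 0.0369 and 0.0380, and 0.777 with an estimated correlation), yet their members moved both ways, with 2 higher and 1 lower, 3 and 1, and 5 and 2 of 18. H2BC3 rose by 1.41, 1.70 and 1.67 (SE 0.22), while H2BC7 was lower (-1.25, -1.14 and -1.30, SE 0.20).

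The MHC class I list was called lower in all 3 treatments (members lower 3, 3 and 8 of 13; 6, 5 and 8 adjusted over the list alone; camera adjusted p = 0.0160, 0.0191 and 0.000674), with the calls for gapmer 1 and gapmer 2 lost after quantile normalization (0.0692 and 0.0527). These calls, and those of the MHC class II, interferon and NF-kB lists, had adjusted p = 0.777 with an estimated correlation. HLA-E was lower (-1.04, -1.04 and -1.38, SE 0.23). The MHC class II list was called with gapmer 2 (2 of 13; 0.0269, lost after quantile normalization at 0.0835, and at percentile 2.92 of random lists matched on level, inside the central 95%) and gapmer 1+2 (9 of 13; adjusted p = 9e-05). The interferon response list was called with gapmer 2 (3 of 28 lower; 0.000674) and gapmer 1+2 (13 of 28 lower, 21 adjusted over the list alone; 4.55e-06), and ISG15 was lower (-1.25, -1.69 and -2.16, SE 0.27). NF-kB targets were called with gapmer 2 (0.0296) and gapmer 1+2 (0.000674). CFLAR, an inhibitor of caspase 8, was lower (-1.37, -1.68 and -2.27, SE 0.26), and against the list CD83 rose by 0.93 with gapmer 2.

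With gapmer 1+2, B-cell identity (adjusted p = 0.000674), B-cell receptor signalling (0.00858) and B-cell activation (0.00216; 10 of 20 lower) were called lower as lists. These calls, and those of the integrated stress response, BCL2 family and oxidative phosphorylation lists, had adjusted p = 0.777 with an estimated correlation, and B-cell receptor signalling lay inside the central 95% of random lists matched on level (percentile 3.53). CD24, a surface glycoprotein of B cells, was lower (-1.14, -1.48 and -1.89, SE 0.22), LYN, a kinase of the receptor, was lower (-0.78, -0.99 and -1.26, SE 0.20), and CCR7, a chemokine receptor, fell by 1.56 ± 0.23 (SE) with gapmer 1+2. The integrated stress response was called with gapmer 1 (0.0164) and gapmer 1+2 (0.0101), both lost after quantile normalization (0.0835 and 0.0783), and WARS1, a tRNA synthetase, was lower (-0.92, -1.13 and -0.95, SE 0.21; after quantile normalization -0.53, -0.75 and -0.36). Also lost after quantile normalization were the gapmer 1+2 calls of the BCL2 family (0.0373, then 0.0709), in which MCL1, an anti-apoptotic member, was lower (-0.81, -1.08 and -0.92, SE 0.17), and of oxidative phosphorylation (0.0480, then 0.326; percentile 14.2).

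Further genes with the highest mean changes were SOX10 (3.12, 3.08 and 2.45, SE 0.26), STYXL2 (mean 2.67), RN7SL81P (2.61), RN7SL395P (2.59), GOLGA8J (2.38), KANTR (2.25), BTF3P2 (2.13), MIR6865 (2.09) and MIR1185-1 (2.02). The lowest were RN7SKP204 (-3.64), RN7SKP203 (-3.10), RN7SKP85 (-2.71), RN7SKP290 (-2.56), RN7SL811P (-2.35), RN7SKP112 (-2.29), RN7SKP36 (-2.27), PCBP1 (-2.21) and RNU6-271P (-2.20). Among markers of other cell types, the myeloid genes FCN1 and CD163 moved apart: FCN1 was lower (-1.39, -1.46 and -1.36, SE 0.18), and CD163 rose by 1.00, 0.90 and 1.03 (SE 0.25). Of 780 microRNA units, 23 were higher and 25 lower in all 3 treatments, against 2090 and 2728 of all 67896 units. Counts of called units were 9028 (4204 higher, 4824 lower), 8307 (3532 higher, 4775 lower) and 11058 (4741 higher, 6317 lower), with 4480, 4191 and 5594 changed at least 2-fold. With any 1 array left out the counts were 4939 (without gapmer 1 replicate 3) to 5758, 4384 (without gapmer 2 replicate 2) to 5377 and 6840 (without gapmer 1+2 replicate 2) to 10546. They were 5376, 4968 and 7340 with a filter at the 75th percentile, 18577, 15961 and 20544 against the CYTOR scrambled arrays and 23156, 19361 and 25112 against the LINC00158 scrambled arrays. Counts against other scrambled arrays came from a joint fit of all 36 arrays. In that fit the RP11-161H23.5 scrambled arrays themselves gave 9144, 8309 and 10876. With only the groups of the contrast gapmer 1+2 gave 5782. Here too the compared arrays are of different sets.

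**Figure D4:**
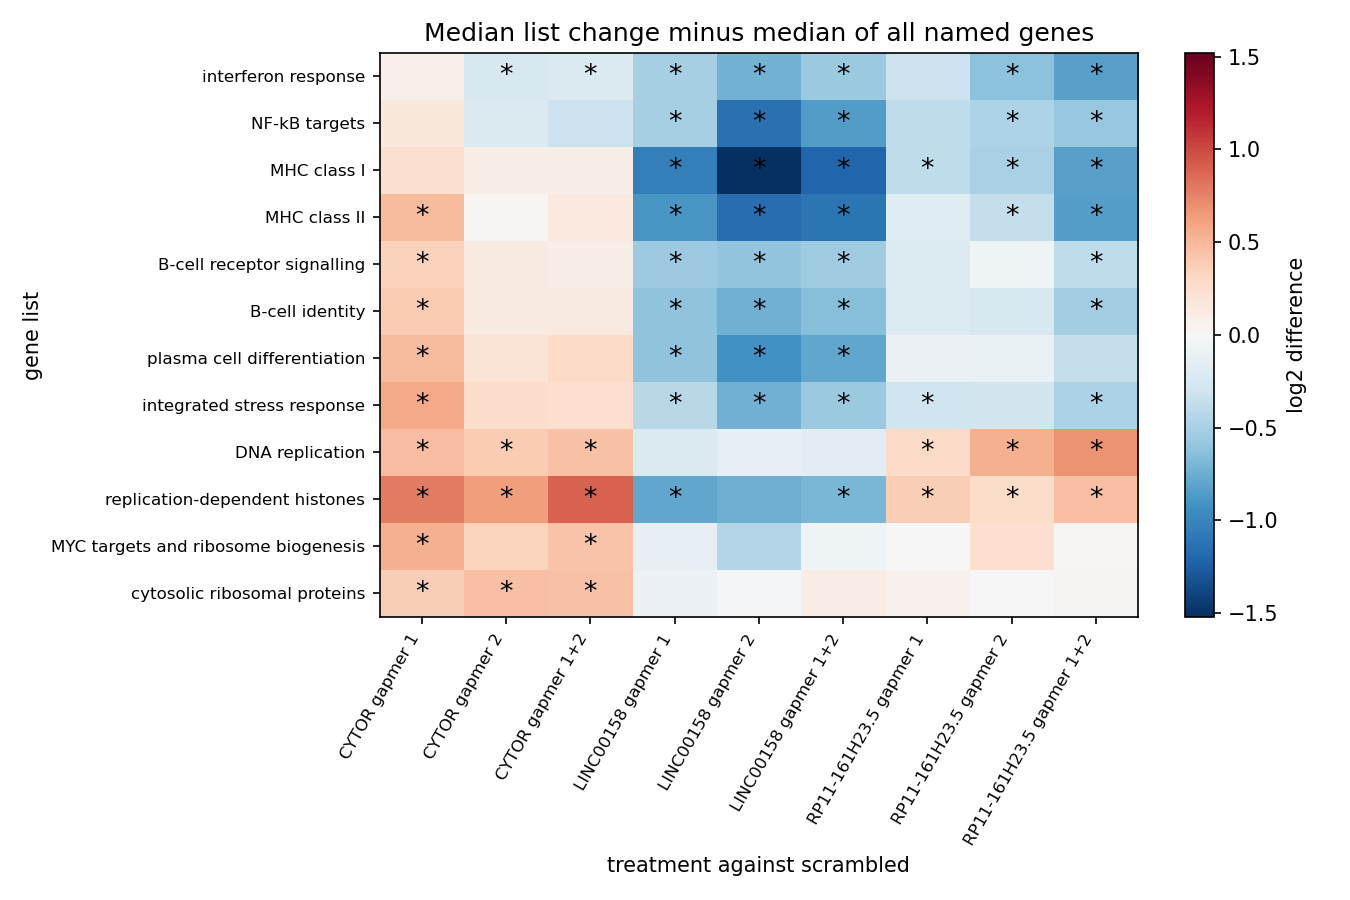
Colours give the median log2 change of each gene list minus the median of all named genes (rows, lists; columns, 9 treatments against scrambled), and a star marks a camera adjusted p under 0.05 at the preset correlation. MHC class I with LINC00158 gapmer 2 was lowest at -1.52; no star held with an estimated correlation, and 35 of all 83 calls were lost after quantile normalization.

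Because changes depended on signal level, each list was also set beside random lists matched on level, a test chosen after seeing the data. On the side of the call, the list's median lay outside the central 95% of the random lists for 51 of the 83 calls, namely 13 of 26 for CYTOR, 19 of 35 for LINC00158 and 19 of 22 for RP11-161H23.5. LINC00158 calls of MHC class I (0.09, 0.00 and 0.02) and MHC class II (0.83, 0.28 and 0.07) lay outside, as did DNA replication in all treatments of CYTOR (99.9, 99.9 and 100) and RP11-161H23.5 (99.8, 100 and 100).

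Comparing gapmer 1 with gapmer 2 asks whether both oligonucleotides against a target act alike, and these comparisons lie within a set. By limma, 0 units differed in any experiment (unadjusted p under 0.05: 4343 units for CYTOR, 2866 for LINC00158 and 4331 for RP11-161H23.5). Between gapmer 1+2 and the mean of the single gapmers limma called 0 units (4462, 3008 and 5686 at unadjusted p under 0.05). For RP11-161H23.5 that count was 60 without gapmer 1+2 replicate 1, and 1 unit differed between the single gapmers without gapmer 1 replicate 2. A p that misses the threshold does not show that the gapmers act alike. The contrast of gapmer 1+2 also does not separate the combination from a possibly higher total amount of oligonucleotide.

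Units called the same way with both single gapmers numbered 6124 for CYTOR (637 higher, 5487 lower), 5821 for LINC00158 (2452 higher, 3369 lower) and 5634 for RP11-161H23.5 (2447 higher, 3187 lower, and 1 opposite). Independent lists of these sizes would share 22.1 higher and 955 lower, 213 and 447, and 219 and 339, and the simulations without change gave 0. That 0 was fixed in advance, since almost no unit is called where nothing changes. The number for independent lists leaves out the shared scrambled arrays. Neither shows how much overlap the shared arrays alone would give lists of these sizes. The covariance of the changes of both gapmers was 0.262, 0.418 and 0.272, against 0.0551, 0.0598 and 0.0465 in the simulations, in which shared scrambled arrays alone gave r = 0.50. Without LINC00158 gapmer 1 replicate 1 that experiment's overlap was 12800, and without scrambled replicate 1 it was 1836. The CYTOR overlap was 3524 without gapmer 1 replicate 2, and that of RP11-161H23.5 was 3381 without scrambled replicate 1. Called with all 3 treatments were 439 units higher and 3870 lower for CYTOR, among them OR10Q1 and ISL1. For LINC00158 they were 2040 and 2783, with MYEOV and PCBP1, and for RP11-161H23.5 they were 2090 and 2728, again with MYEOV and PCBP1.

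Comparing experiments asks which changes belong to a target. The changes in the LINC00158 and RP11-161H23.5 experiments overlapped: 1143 units were called the same way in all treatments of both (472 higher, 671 lower) and 4 in opposite ways, where independent lists would give 52.6, 118 and 157. MYEOV (mean changes 4.25 and 3.72), SOX10 (3.31 and 2.88), RN7SL395P (3.44 and 2.59) and EFHD1 (2.15 and 1.92) were higher in both. PCBP1 (-3.19 and -2.21), ISG15 (-2.83 and -1.70) and ARL2, a small GTPase (-2.66 and -1.61), were lower in both. Across units, which are not independent replicates, mean changes correlated at Pearson r = 0.470 and Spearman rho = 0.435. CYTOR shared 317 units with LINC00158 in direction and 223 in opposition (r = -0.0256, rho = 0.00572), and 350 and 212 with RP11-161H23.5 (r = 0.0957, rho = 0.103). Independent lists would give 7.76 higher, 174 lower and 113 opposite for the former pair and 7.77, 174 and 115 for the latter, so opposite calls exceeded that number too. Called the same way in all 9 contrasts were 5 units higher and 98 lower.

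**Figure D5:**
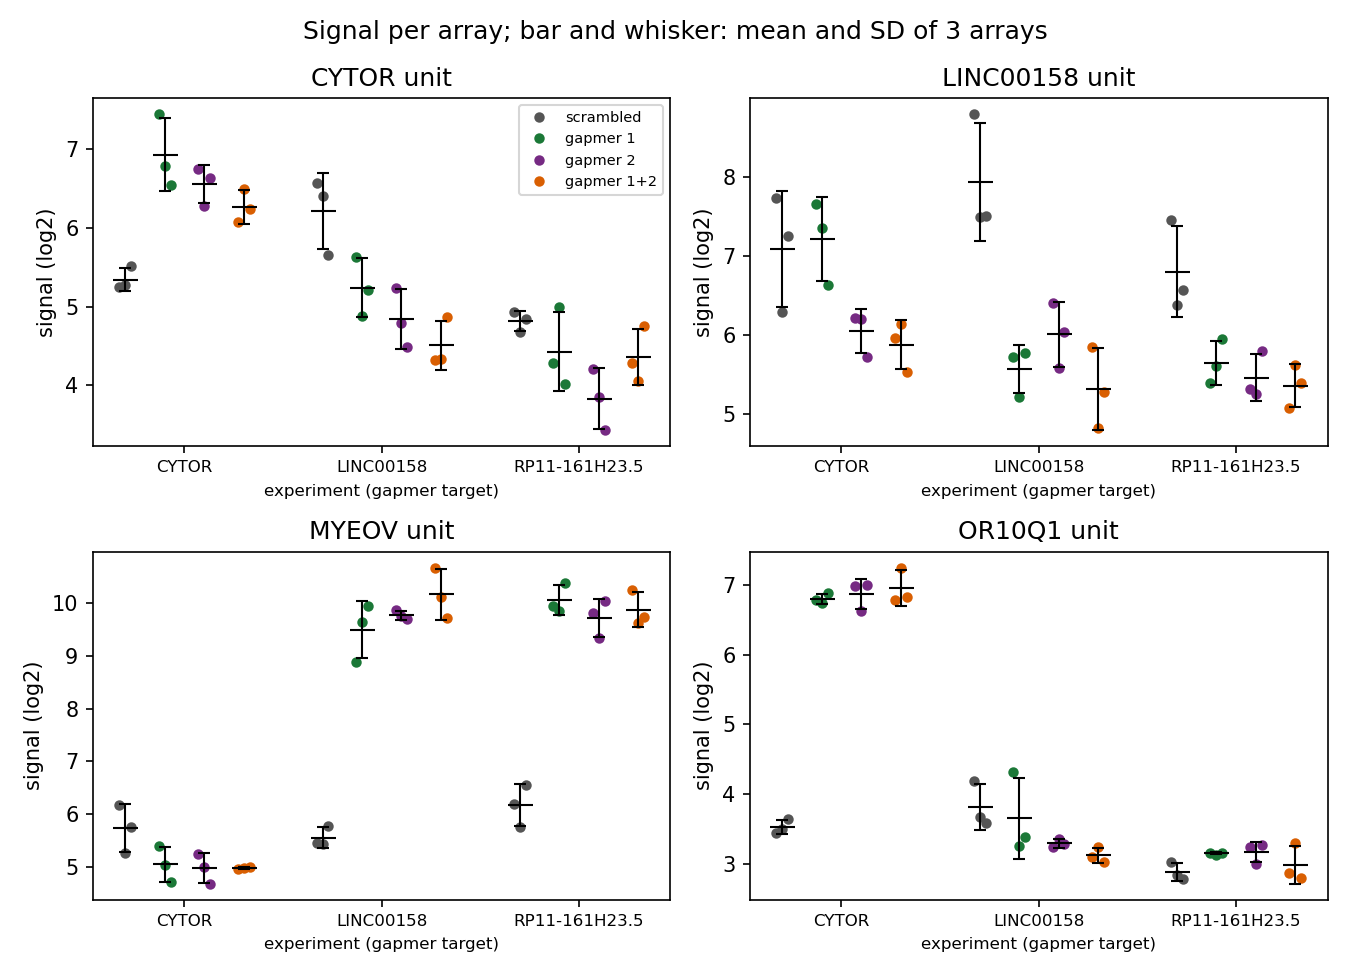
Points give the log2 signal of 4 units on each array by experiment and treatment, with the mean and SD of 3 arrays. The CYTOR unit was at 5.34 with scrambled gapmer and at 6.93, 6.56 and 6.27 with CYTOR gapmers, and MYEOV means were at 9.49 or above with LINC00158 and RP11-161H23.5 gapmers.

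The scrambled groups received the same kind of control in all 3 experiments and lie in 1 set. By limma, LINC00158 and CYTOR scrambled groups differed in 0 units (6602 at unadjusted p under 0.05). The RP11-161H23.5 scrambled group differed from the CYTOR group in 1040 units (193 higher, 847 lower) and from the LINC00158 group in 3525 (852 higher, 2673 lower), with MIR4740 at 12.19 ± 0.48 there and 5.79 ± 0.44 in the LINC00158 group. Over the 3 groups the F test called 1970 units. Treatments of different experiments, which lie in different sets, differed in 8317 to 26252 units.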

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

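For the first 2 patterns the tests of label exchange, shared signal, other scrambled arrays, shared controls, a general gapmer effect and separate sets were chosen only after the result was seen. All differences between experiments here also compare arrays of different sets.

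The change of many units differed between experiments by a test of the difference itself (interaction in a limma fit of all 36 arrays): 17503 units between LINC00158 and CYTOR, 12929 between RP11-161H23.5 and CYTOR, and 6562 between RP11-161H23.5 and LINC00158. The CYTOR unit's change was different by -2.59 in the LINC00158 experiment (adjusted p = 2.18e-06) and by -1.85 in the RP11-161H23.5 experiment (adjusted p = 0.000207), each relative to CYTOR. The LINC00158 unit's change was different by -1.60 in its own experiment relative to CYTOR (adjusted p = 0.00675), and the RP11-161H23.5 change of that unit was not shown to differ from it (0.99; adjusted p = 0.135). In the CYTOR experiment the LINC00158 unit's change ran from 0.13 with gapmer 1 to -1.21 with gapmer 1+2. The MIR4740 change differed by 9.75 between LINC00158 and CYTOR (adjusted p = 2.4e-08), by 4.29 between RP11-161H23.5 and CYTOR (adjusted p = 0.00168) and by -5.46 between RP11-161H23.5 and LINC00158 (adjusted p = 0.000849). The MYEOV change differed by 4.99 between LINC00158 and CYTOR (adjusted p = 1.12e-11) and by 4.45 between RP11-161H23.5 and CYTOR (adjusted p = 1.05e-10). Between RP11-161H23.5 and LINC00158 neither the CYTOR unit (0.74; adjusted p = 0.152) nor MYEOV (-0.54; adjusted p = 0.297) was called.

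The CYTOR unit was higher in the arrays labelled CYTOR gapmer, against the purpose of the treatment. An exchange of labels between the scrambled and a gapmer group would leave that gapmer group unlike the others, yet 0 units differed between the gapmer groups. This test covers only that exchange. An exchange of all treated arrays with those of another experiment would leave the gapmer groups alike and was not tested. Signal shared with MIR4435-2HG is argued against by that unit's change of at most -0.73, and the scaling of the arrays by a change of at least 1.21 after quantile normalization. What stays open is a low signal in this experiment's scrambled arrays, since the other controls point both ways, with a change as small as 0.057 against the LINC00158 and of at least 1.45 against the RP11-161H23.5 scrambled arrays, and an error specific to a set. A biological rise of the RNA cannot be told apart from these, because no other measure of CYTOR was used here.

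Treated groups of an experiment shared many changes against scrambled, and limma called 0 units between them, which does not show that they act alike. The spread of the shared scrambled arrays may give part of this sharing but not all. The covariance of gapmer 1 and gapmer 2 changes was at least 4.75 times the simulated one. The simulation drew only the spread within groups and gave the scrambled group no offset of its own. It therefore cannot exclude that such an offset gives the sharing. An effect of any gapmer whatever its target is argued against as the whole cause by r = -0.0256 between the CYTOR and LINC00158 changes. Separate summaries of scrambled and treated arrays are consistent with the identical values, which were at least 4.45 times as frequent within a set as between scrambled and treated groups. Whether unit-specific offsets between the sets make up the changes stays open. Changes of 2 units of a gene correlated at r = 0.143 for CYTOR, 0.0449 for LINC00158 and 0.0731 for RP11-161H23.5. The same weak test gave 0.148, 0.197 and 0.134 for scrambled groups within a set. The LINC00158 and RP11-161H23.5 values lay below all of these, and the CYTOR value did not. The treatment and the set thus cannot be told apart.

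The LINC00158 and RP11-161H23.5 changes were shared in part, with 1143 units called the same way in all treatments of both. A shift that depends on signal is argued against by r = 0.457 after quantile normalization, and the 7SK and 7SL copies alone by r = 0.467 without them. The 1 array that stood apart, LINC00158 gapmer 1 replicate 1, is argued against by r = 0.456 without it. Offsets of the scrambled set alone are argued against as the whole cause, since the CYTOR changes use the same set and gave r of -0.0256 and 0.0957 with these. A response common to both target RNAs and offsets shared by both treated sets were not tested and cannot be told apart.

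Splits of the arrays into other groups gave the following. For each treatment against scrambled the 10 splits of 6 arrays were too few for a share under 0.05: the real split alone (1 of 10) gave the reported count, and the highest other count was 0. For gapmer 1 against gapmer 2 all 10 of 10 splits gave 0, and for gapmer 1+2 against the single gapmers all 84 of 84 gave as many as the real 0, with a highest other count of 0 for CYTOR and LINC00158 and 1 for RP11-161H23.5. Units called with both single gapmers numbered 6124, 5821 and 5634, and the highest other was 0 (1 of 100). For the calls shared between experiments, 1810 summed over the 3 pairs of experiments and 1489 different units, the highest other was also 0 (1 of 100). As other splits of treated and scrambled arrays gave 0 calls, regrouping leaves little or nothing to share, so this does not show that either kind of sharing exceeds chance. For the scrambled groups the real grouping alone (1 of 100) reached the count of 1970 units, and the highest other count was 647. This holds for the count and excludes chance for no single unit. For gene lists, 4 of 100 regroupings reached the real 83 of 252 list-by-contrast calls, and the highest other gave 95. The real split of scrambled and treated arrays is also a split between sets, so no result of these splits favours the treatment over the set.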

How the results depend on the processing

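Other scrambled arrays as controls, and fits without 1 array that stood apart, were chosen after seeing the data. Values against other scrambled arrays came from a joint fit of all 36 arrays, so they differ from the main values in the fit too. Over all alternatives, the reported counts and target values came out 251 times on the same side of their threshold or within 1.5 times the count, 106 times beyond that, 12 times without their call and never reversed. The cause was not tested except where fewer units or arrays are the construction. Arrays limit small changes near background, where the filter removes units. Results planned for the RP11-161H23.5 target unit were not run. With a filter at the 75th percentile, which tests fewer units, counts were 4554, 5288 and 3340 for the CYTOR treatments (both gapmers 3280), 4795 for LINC00158 gapmer 1, 5376, 4968 and 7340 for RP11-161H23.5 (both 3532) and 3007 between scrambled groups. Quantile normalization gave 4082, 4621 and 2909 for CYTOR (both 2457), 1071 calls shared, summed over pairs of experiments, 1188 between scrambled groups and 50 list calls. Only the groups of the contrast, hence fewer arrays, gave 4729, 2484 and 3665 for CYTOR, 164 for LINC00158 gapmer 1 (target -2.36, adjusted p = 0.0650) and 5782 for RP11-161H23.5 gapmer 1+2. All 36 arrays in one fit gave 13297 and 15923 for LINC00158 gapmer 1 and gapmer 1+2, and 2, 1 and 1 units for gapmer 1+2 against single gapmers (CYTOR, LINC00158, RP11-161H23.5). Trend and robust gave 3042 between scrambled groups. The replicate block gave the CYTOR unit 0.92 with gapmer 1+2 (adjusted p = 0.0599). An estimated correlation gave 0 list calls.

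Against LINC00158 scrambled arrays CYTOR gapmer 2 and gapmer 1+2 gave 14965 and 10905 units, and the CYTOR unit 0.72, 0.35 and 0.057 (adjusted p = 0.0771, 0.407 and 0.920). Against RP11-161H23.5 scrambled arrays CYTOR counts were 17780, 16439 and 16618, and the LINC00158 unit with gapmer 2 was -0.79 (adjusted p = 0.167). RP11-161H23.5 counts were 18577, 15961 and 20544 against CYTOR and 23156, 19361 and 25112 against LINC00158 scrambled arrays. Reversed were the mean changes over the CYTOR treatments of CD83 (-0.20, but 0.087 under quantile normalization) and TNFAIP8 (0.034, but -0.043 to 0.133 when 1 array was left out, negative without scrambled replicate 3, gapmer 1 replicate 2 or gapmer 2 replicate 2). Leaving out each replicate gave 4334 to 7117, 6019 to 7902 and 3027 to 5070 for CYTOR (both 3524 to 5152; unit 1.33 to 1.78, 1.12 to 1.35, 0.81 to 1.02); 2133 to 17407, 4888 to 7329 and 3202 to 6390 for LINC00158 (both 1836 to 12800; unit -2.58 to -1.93, -2.14 to -1.49, -2.89 to -2.19); and 4939 to 5758, 4384 to 5377 and 6840 to 10546 for RP11-161H23.5 (both 3381 to 3832; gapmer 1 against 2, 0 to 1; gapmer 1+2, 0 to 60). Without LINC00158 gapmer 1 replicate 1, calls shared, summed over pairs of experiments, were 2304 and list-by-contrast calls 86, against 1810 and 83. There were 423 entries, each a named gene in 1 experiment. An entry was counted as kept when called in at least as many of the 3 treatments as before. Quantile normalization kept 267, the replicate block 338, no filter 358, one fit of all arrays 360 and trend and robust 389. The 75th percentile filter kept 379 of the 387 it tested. Leaving out 1 array lowered the number of called treatments in 1941 of 5076 cases and reversed the mean change in 3. As fewer arrays alone can lower it, this does not show that calls depend on particular arrays.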

Other observations

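The counts of 7SK and 7SL copies and the units with 1 value on several arrays of a group or set were looked at only after the results were seen. The p53, oxidative stress and cholesterol lists were not called, though members changed. With LINC00158 gapmer 2 and gapmer 1+2, 5 of 23 p53 targets were lower each (10 and 7, with 1 and 0 higher, adjusted over the list alone). NQO1, a quinone reductase of the oxidative stress response, rose by 1.04, 0.96 and 1.20 (SE 0.20, n = 3) with the CYTOR treatments and was lower (-1.09, -1.48 and -1.15, SE 0.23) with the LINC00158 treatments. MT2A, a metallothionein, was lower in the CYTOR (-1.06, -1.14 and -1.37, SE 0.22) and RP11-161H23.5 experiments (-0.90, -1.25 and -1.19, SE 0.26). The p53 targets MDM2 and CDKN1A fell with LINC00158 gapmer 2 (-2.02 and -1.52) and gapmer 1+2 (-1.83 and -1.32). XPC, a DNA repair gene, rose by 1.10, 1.44 and 0.96 (SE 0.21) with the CYTOR treatments. SREBF2, which controls cholesterol synthesis, was lower (-1.54, -2.01 and -1.63, SE 0.42) with the LINC00158 treatments.

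The lists never called, in any of 9 contrasts, were nucleic acid sensing (lowest camera adjusted p = 0.0998), p53 targets (0.0629), oxidative stress response (0.0574) and cholesterol biosynthesis (0.0751), and the markers of T and NK cells (0.228), myeloid cells (0.106), erythroid cells and platelets (0.644) and stromal and epithelial cells (0.230). After quantile normalization the p53 targets were called with CYTOR gapmer 1+2 (0.0418), and so were the NF-kB targets (0.0199). Some members still moved. The nucleic acid sensor AIM2 was lower (-1.24, -1.17 and -1.31, SE 0.27) with the RP11-161H23.5 treatments, and TLR7 was lower (-1.47, -1.36 and -1.87, SE 0.39) with the LINC00158 treatments. KRT19, an epithelial keratin, was lower (-0.90, -1.24 and -1.27, SE 0.19) in the RP11-161H23.5 experiment, and NKG7, an NK cell gene, was lower (-0.94, -1.08 and -0.92, SE 0.27) in the LINC00158 experiment.

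Of 182 copies of 7SK tested in the LINC00158 experiment, 7 were higher and 24 lower in all 3 treatments, and 7 and 21 after quantile normalization. Of 530 copies of 7SL, 25 were higher and 41 lower, which turned to 34 and 16 after quantile normalization. Some bright units held 1 value on all arrays of a group: RN7SKP204 read 15.91 on each of the 3 LINC00158 scrambled arrays, and PCBP1 read 15.25 on each of the 3 RP11-161H23.5 scrambled arrays. PCBP1 values also recurred between groups of a set. It read 15.25 on CYTOR scrambled replicates 2 and 3. Arrays of every treatment read 15.78 for CYTOR, 12.25 for LINC00158 and 13.07 for RP11-161H23.5. For its changes too, the set and the treatment cannot be told apart. The CYTOR unit fell with LINC00158 gapmer 2 and gapmer 1+2 (-1.37 and -1.70; adjusted p = 0.0152 and 0.00799) and fell by 0.99 with RP11-161H23.5 gapmer 2 (adjusted p = 0.0435). Replicate numbers did not pair the arrays, since residuals of arrays with the same number correlated at a mean r of -0.0146, 0.0104 and 0.00413 in the 3 experiments.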
